A study of Mus musculus with 6 samples.

How the data were processed

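Uterine RNA in 6 samples from female mice at 3.5 days post coitum, 3 Stat3 f/f and 3 Stat3 d/d, was labelled with biotin as cRNA and hybridised to Affymetrix arrays, per the labels' protocols. The groups come from the source names given in the labels, and replicate numbers from the sample titles. The submitters' processing notes name RMA (robust multi-array average, a background correction, quantile normalization and summary of probes); no version is given. The deposited values are probe set intensities on a linear scale. RMA gives log2 values, so they had been returned to a linear scale, a step that no source used here records; the plan had assumed log2 values or, failing that, log2(value + 1). Genome build and annotation are not given in the sources used here.

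The deposited table is a selection, unstated in the sources used here. All 1382 probe sets have a ratio of arithmetic group means of at least 1.5 (smallest 1.50), no probe set has overlapping groups, and 13 have a p over 0.05 from their own spread on the log2 scale. Probe sets outside this selection were not analysed here, so a gene missing from the table cannot be called unchanged, enrichment against the whole array cannot be tested, and the scaling between arrays cannot be checked. Arrays differed by an SD of 0.34 to 0.48 (log2) within groups and 1.07 to 1.30 between groups over these selected probe sets, and no pair held the same values throughout.

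Probe sets were named through the platform's annotation: 1191 had 1 gene symbol (987 genes), 57 had several and 134 were unnamed here. Of the identifiers, 1186 matched in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols; that table also gave the order of genes along chromosomes, and no coordinates are printed. A gene with several probe sets in the table was represented by the one with the highest mean over all 6 arrays. A brighter probe set outside the table could not be chosen. Of 163 such genes, 15 had probe sets in opposite directions.

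Values were taken as log2(intensity + 1), so changes of dim genes are understated. Stat3 d/d was compared with Stat3 f/f by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment over the table and a threshold of 0.05. All changes are Stat3 d/d minus Stat3 f/f. Gene lists with at least 5 genes in the table were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry. Camera compares a list with the other genes of this table, and fry asks whether its genes move one way. As the table holds only genes selected to differ, fry calls almost any list that leans one way. It called 13 of 15 lists, a count that therefore adds little. Figures were drawn with matplotlib 3.10.9.

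Named genes were fixed by a rule written before the data were examined: Stat3, the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, leaving out unnamed predicted genes (1 rise was passed over), and in each list up to 4 members with the smallest adjusted p. Genes outside this rule were chosen after their values were seen: Osmr, Jak2, Xaf1, Ifitm1, Pgr, Ramp3, Dio2 and Cd3g in the report, and those named as such in the closing section.

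The fits were tested on simulated data for this comparison: 45000 probe sets with 200 changed, with levels and spread drawn from the real table. Of 66 probe sets changed 4-fold, 64 were recovered (97.0%), of 67 changed 2-fold 14 (20.9%), and of 67 changed 1.5-fold 0, with 2 false calls. The spread comes from selected probe sets and can therefore be too small. Lists were simulated among 1000 of these probe sets, and camera with the preset correlation called 0 of 200 unchanged lists. These probe sets were drawn independently and without the selection of the table. That count therefore does not test how correlation between genes or the selection affects the list calls. Alternatives were quantile normalization, median centring, variance models, array weights, a filter on dim probe sets, leaving out each array, the replicate number as a block, other thresholds, the mean of a gene's probe sets, and, chosen after the data were seen, no pseudocount, no variance moderation, 45000 assumed tests and the STAT3 list without Stat3.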

Results

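RNA from the uteri of mice at 3.5 days post coitum, shortly before implantation, was measured on Affymetrix expression arrays. Mice with intact floxed alleles of Stat3 (Stat3 f/f, 3 arrays) were compared with mice carrying the deleted alleles (Stat3 d/d, 3 arrays). Stat3 encodes a transcription factor that is activated by cytokines of the interleukin-6 family, and the series concerns its loss in relation to inflammation and endometriosis. The table analysed here holds 1382 probe sets, each with a normalized intensity on every array, between 2.47 and 4352. All 1382 differ at least 1.5-fold between the group means and have groups that do not overlap, which chance gives for 10% of probe sets in a comparison of 3 against 3, so the table had been selected on this comparison. The number of arrays limits the precision, and as the labels do not say that each array came from a separate animal, p-values measure only the spread between these samples, which may be technical.

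Stat3 itself was lower in every Stat3 d/d array. The brighter of its 2 probe sets read 287 ± 60.8 in Stat3 f/f and 118 ± 14.9 in Stat3 d/d (mean intensity ± SD, n = 3 arrays each), or 41.0% of the Stat3 f/f level. The log2 change was -1.27 (SE 0.20, adjusted p = 0.000352). The other Stat3 probe set fell from 252 ± 52.6 to 107 ± 5.94, or 42.6%. Where either probe set lies relative to the deleted part of the gene was not examined, so they check the labels only as far as the transcript read by them depends on the deletion.

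The first comparison asked which transcripts differed between the uteri of the 2 groups. Interferon-induced GTPases were among the largest rises in Stat3 d/d. Gbp6 rose 11.3-fold (log2 change 3.50, SE 0.21), from 31.9 ± 6.58 to 371 ± 68.1, and Iigp1 rose 10.7-fold (3.42, SE 0.17), from 86.2 ± 10.1 to 925 ± 25.6 (SD, n = 3). Gbp2b and Gbp8, of the same guanylate-binding protein family as Gbp6, rose by 3.05 (SE 0.48) and 2.98 (SE 0.27), and without Stat3 f/f replicate 4 the value of Gbp2b was 3.74. Nlrc5, a transactivator of MHC class I genes, rose by 2.97 (SE 0.16), and the tripartite motif genes Trim34a and Trim30d by 3.39 (SE 0.17) and 3.29 (SE 0.20). A second Trim34a probe set went the other way, at -0.61, and a second one of Trim30d gave 0.56; averaged over probe sets the changes were 1.39 and 1.92.

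By the probe set that stands for each gene, the largest rise of a named gene was in Ang. This ribonuclease, angiogenin, rose from 14.7 ± 15.4 to 246 ± 10.8, a log2 change of 4.41 (SE 0.49), which was 5.18 without Stat3 f/f replicate 1. Ovgp1, the oviductal glycoprotein and the only gene in the table from the ovary and oviduct list, rose from 20.2 ± 12.02 to 359 ± 128, a log2 change of 4.23 (SE 0.43). Klra8, an activating receptor of natural killer cells, rose by 3.52 (SE 0.25), and the ectonucleotidase Enpp3 by 2.95 (SE 0.32). The Klra8 mean in Stat3 f/f was 4.27 ± 0.22, near the lowest intensity of the table (2.47), against 63.0 ± 26.9 in Stat3 d/d. Rps9, a protein of the small ribosomal subunit, rose by 4.31 (SE 0.32). The probe sets of Ang, Ovgp1, Klra8 and Rps9 carry suffixes that Affymetrix gives to probe sets sharing sequence with other transcripts. The same holds for C2, H2-D1, Prap1, Wnt5b, Fmod, Cldn3, Ighm, Upk3b and Lyz1, named below. Averaged over their probe sets, Ang rose by 3.03 and Enpp3 by 1.87, with the lowest probe set at 1.23 and 0.53.

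The deepest fall was in Gdpd3, a phospholipase of the glycerophosphodiester family, from 487 ± 40.6 to 13.7 ± 3.86, a log2 change of -5.09 (SE 0.21). Lcn2, an iron-scavenging lipocalin of the acute phase, fell from 164 ± 58.7 to 15.2 ± 5.18 (-3.33, SE 0.30), and Cfi, the protease that inactivates complement C3b, from 98.9 ± 52.0 to 8.36 ± 1.19 (-3.31, SE 0.30). The serine protease inhibitor Serpina3n fell by 2.49 (SE 0.51) on the log2 scale, and by 3.28 without Stat3 f/f replicate 4. Spink12, a Kazal-type protease inhibitor, fell by 2.23 (SE 0.48), and by 2.94 without Stat3 f/f replicate 2. Rbp7, a retinol-binding protein, changed by -2.52 (SE 0.20), and Itga9, the integrin alpha 9 chain, was 3.99-fold lower. Tmem87a (-3.54), Cuedc1 (-2.33), Paip1 (-2.22), Mtrex (-2.17) and Hddc3 (-2.07) completed the 12 largest falls, with SEs from 0.16 to 0.26.

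**Figure D1:**
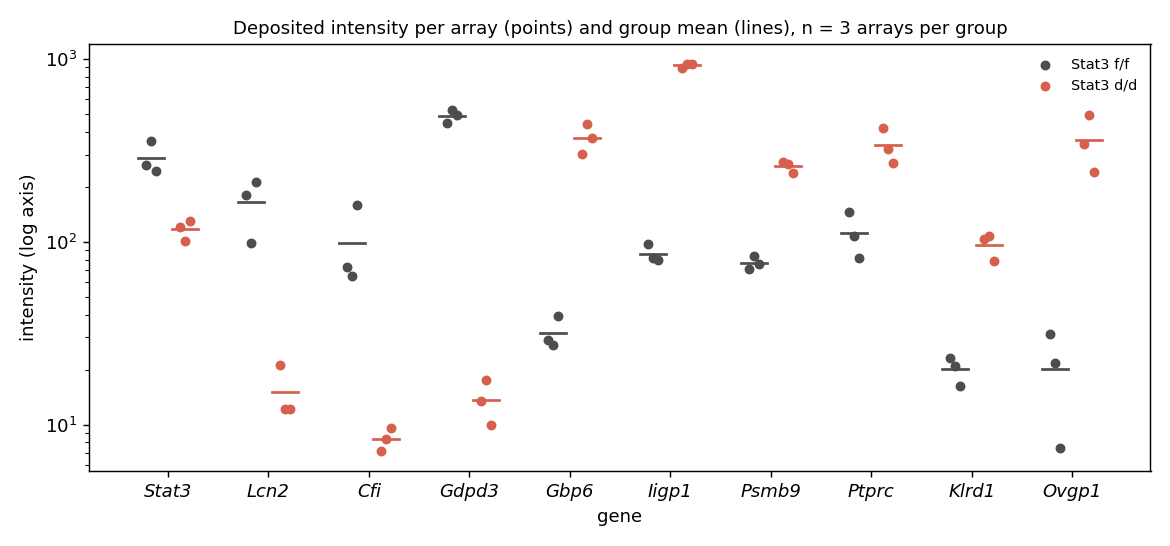
Deposited intensity (log axis) of 10 genes on each of the 6 arrays, Stat3 f/f in grey and Stat3 d/d in red, with a point per array and a line at the group mean (n = 3). The groups do not overlap for any gene shown; Gdpd3 fell from a mean of 487 to 13.7, and Gbp6 rose from 31.9 to 371.

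Across the table, 931 probe sets were higher and 451 lower in Stat3 d/d, and all 1382 passed an adjusted p of 0.05 in limma, with the largest at 0.0273. By gene, 660 of 987 were higher and 327 lower, and 54 genes rose and 11 fell at least 4-fold by the probe set that stands for each gene. Because of the selection these passes add little: in a simulation without any change, 662 of the 667 probe sets (99.3%) that met the same selection also passed. When 45000 tests were assumed, about the size of such an array, 518 probe sets (387 higher, 131 lower) passed, against 18 in that simulation. Without variance moderation these counts were 17 and 0. The simulated probe sets vary independently, with a spread from selected probe sets and no difference in scaling between the groups. The contrast therefore cannot show how many probe sets truly differ. After centring each array on its median in this table, 422 probe sets past the threshold were higher and 451 lower. After quantile normalization these were 436 and 451. The share of all probe sets that were higher stayed at 67.4% under both. The scalings moved the median change of all probe sets from 0.70 to 0.24 and 0.25, and which scaling is right cannot be read from a selected table. Lowering the changes in this way takes calls from small rises but not from falls. A lost rise or a kept fall under these scalings therefore says little about the gene itself.

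The next comparisons asked how groups of genes fixed before the data were examined behaved. Of 30 lists, 15 had at least 5 genes in the table and were tested against the other genes of the table. Of these, 10 passed with a preset correlation and none with an estimated one, where the smallest adjusted p was 0.250 and 2 lists had an unadjusted p under 0.05. The calls are not all separate results, as several lists share members. Lcn2 stands on the STAT3 and oestrogen lists, Serpina3n on the STAT3 and complement lists, and Cfi on the gland and complement lists. Lgr5 stands on the gland and Wnt lists, and Wnt4 on the oestrogen and Wnt lists. Every list member in the table passed, both over all genes and adjusted over the list alone, as the selection would give. A member missing from the table was not tested here. The table held 34 of the 54 interferon-stimulated genes, 13 of 49 oestrogen-regulated and 7 of 26 gland genes. It held 6 of 48 genes of the STAT3 list, 7 of 40 complement, 7 of 44 Wnt and 7 of 68 extracellular matrix genes. Counts of rises and falls therefore cover only part of each of these lists.

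Genes of STAT3 and interleukin-6 signalling were mostly lower in Stat3 d/d: 5 of the 6 in the table fell, among them the deleted gene itself, and 1 rose. Besides Stat3, Lcn2 and Serpina3n, the transcription factor Cebpb fell by 0.72 (SE 0.18), and the oncostatin M receptor gene Osmr by 0.79 (SE 0.21). The kinase gene Jak2 rose by 0.68 (SE 0.17), and lost its call with either scaling (0.21 after median centring, adjusted p = 0.274). The median change of the list was -1.03 (adjusted p = 0.0142; adjusted p = 0.250 with an estimated correlation). Without Stat3, a setting chosen after the data were seen, 4 of 5 genes fell, with a median of -0.79 (adjusted p = 0.0375; adjusted p = 0.267 with an estimated correlation). The complement and acute-phase genes in the table showed a median of -0.97, with 6 of 7 lower (adjusted p = 0.0142, and adjusted p = 0.250 with an estimated correlation). Among them were Cfi and the protease inhibitor A2m, which fell from 550 ± 293 to 161 ± 39.5 (-1.67, SE 0.33). Complement component C2 rose by 0.75 (SE 0.18), and lost its call when arrays were centred.

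Interferon-stimulated genes rose in Stat3 d/d: 33 of the 34 in the table were higher, with a median log2 change of 1.30. Besides Gbp6 and Iigp1, the immunity-related GTPase Igtp rose 5.47-fold, from 108 ± 21.1 to 587 ± 2.16 (2.45, SE 0.18), and the oligoadenylate synthetase-like gene Oasl2 rose 5.33-fold, from 19.6 ± 2.93 to 108 ± 6.63 (2.41, SE 0.17). The exception was Ifitm1, a membrane protein that restricts viral entry, at -1.04 (SE 0.23). The list passed at an adjusted p of 0.000318, and adjusted p = 0.269 with an estimated correlation. With 45000 assumed tests 22 of its genes passed, all higher, and after median centring 23 were higher past the threshold. Xaf1, a member, had probe sets in opposite directions (1.98 and -3.89).

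Genes of antigen presentation rose alongside: all 8 in the table were higher, with a median of 1.29 (adjusted p = 0.0393; adjusted p = 0.476 with an estimated correlation). Tap1, a subunit of the peptide transporter into the endoplasmic reticulum, rose 3.40-fold (1.77, SE 0.17). The immunoproteasome subunit genes Psmb9 and Psmb8 rose 3.34-fold (1.74, SE 0.17) and 2.39-fold (1.26, SE 0.18), and H2-D1, a classical MHC class I heavy chain, rose from 770 ± 104 to 1973 ± 545 (1.33, SE 0.22). After quantile normalization 6 of the 8 were higher past the threshold, and 7 after median centring. Of these 8 genes, 3 are also interferon-list members.

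Leukocyte markers moved the same way as those lists. All 12 markers of macrophages and dendritic cells in the table rose (median 1.25; adjusted p = 0.0393; adjusted p = 0.596 with an estimated correlation). Among them, the lysosomal protease Ctss rose by 1.79 (SE 0.31), the integrin Itgax by 1.52 (SE 0.18), the pore-forming protein gene Mpeg1 by 1.35 (SE 0.25), and the lectin Cd209a by 0.89 (SE 0.16). All 12 markers of T and NK cells also rose (median 1.30; adjusted p = 0.0230; adjusted p = 0.585 with an estimated correlation). Klrd1, a natural killer receptor chain, rose from 20.2 ± 3.62 to 96.5 ± 15.9 (2.20, SE 0.20), the pan-leukocyte phosphatase Ptprc from 111 ± 32.1 to 337 ± 76.2 (1.61, SE 0.24), the transcription factor Eomes, also the only embryo marker in the table, by 1.40 (SE 0.20), and the interleukin-2 receptor chain Il2rb by 1.36 (SE 0.20). Of the T cell receptor complex genes on the T and NK cell list, only Cd3g was in the table, with means of 4.12 in Stat3 f/f and 11.6 in Stat3 d/d. The rise of that list therefore says little about T cells. The macrophage list lost its call without Stat3 f/f replicate 4 (adjusted p = 0.0532) and without the dimmest genes (0.0736). After quantile normalization 7 macrophage and 11 T and NK cell markers were higher past the threshold, and 8 and 9 after median centring; Cd209a lost its call with the former.

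**Figure D2:**
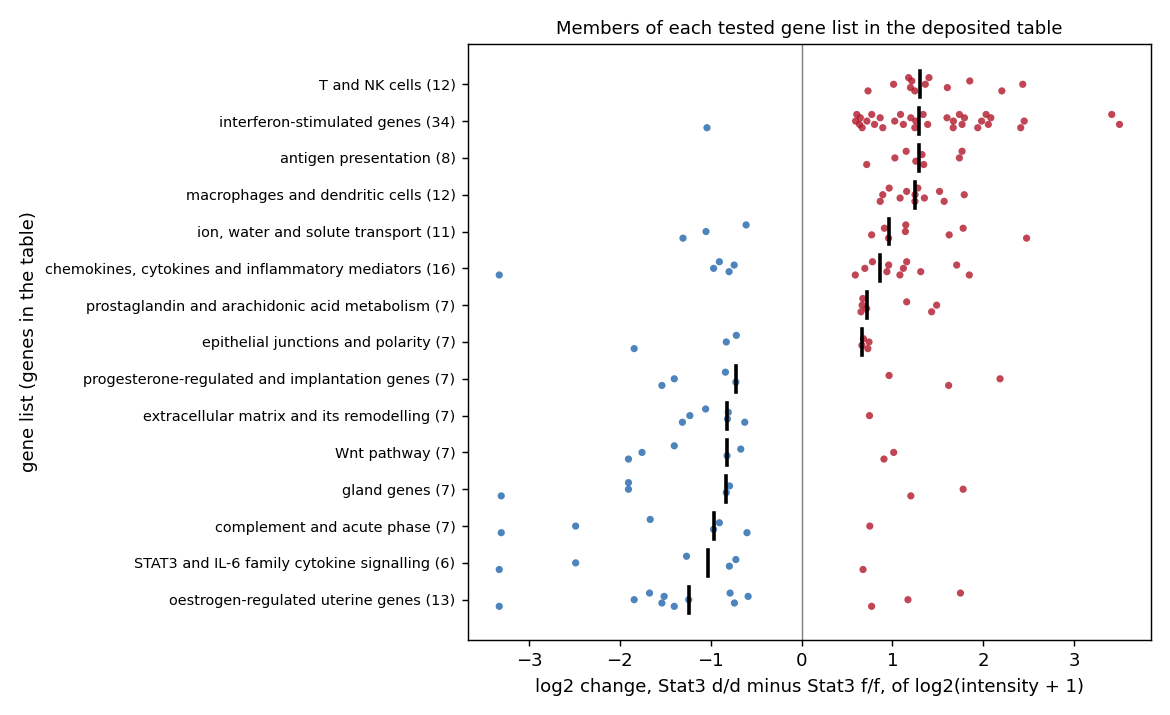
Log2 change (Stat3 d/d minus Stat3 f/f, of intensity plus 1) of each gene of the 15 tested lists, with a point per gene, red above 0 and blue below, and a black bar at the list's median. Medians range from -1.24 for oestrogen-regulated genes to 1.30 for T and NK cell markers; no gene lies near 0 because the table holds only selected genes.

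Among chemokines, cytokines and inflammatory mediators, 11 of 16 genes rose and 5 fell. The interferon-induced chemokine Cxcl10 rose 3.27-fold (1.71, SE 0.24), Il15, a cytokine that maintains natural killer cells, 2.18-fold (1.12, SE 0.17), and the granulocyte growth factor Csf3 2.12-fold (1.08, SE 0.16), while Lcn2 fell. The median was 0.86, and the list did not differ from other genes of the table (adjusted p = 0.865; 0.887 with an estimated correlation). After either scaling 6 were higher and 5 lower past the threshold. All 7 genes of prostaglandin metabolism in the table rose, with a median of 0.72 (adjusted p = 0.135; adjusted p = 0.476 with an estimated correlation). Ptger2, a prostaglandin E2 receptor, rose by 1.49 (SE 0.19), the phospholipase Pla2g4a by 1.43 (SE 0.29), the prostaglandin D synthase Hpgds by 0.72 (SE 0.16) and the prostaglandin transporter Slco2a1 by 0.67 (SE 0.17). After median centring or quantile normalization 2 of the 7 passed, and Hpgds and Slco2a1 did not.

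Oestrogen-regulated uterine genes in the table were mostly lower in Stat3 d/d: 10 of 13 fell and 3 rose. Their median was -1.24 (adjusted p = 0.00744, and adjusted p = 0.267 with an estimated correlation). Without Stat3 f/f replicate 4, the array with the highest Ramp3, Dio2, Wnt4, Gjb2 and Inhbb, the median was -0.89 and the list passed at an adjusted p of 0.00277. Besides Lcn2, the peptidylarginine deiminase Padi1 fell by 1.67 (SE 0.26) and Inhbb, an activin and inhibin subunit, from 209 ± 82.1 to 69.0 ± 17.9 (-1.54, SE 0.29). The growth factor Fgf1 rose by 1.75 (SE 0.18). Of progesterone-regulated and implantation genes, 4 fell and 3 rose (median -0.72; adjusted p = 0.257; adjusted p = 0.608 with an estimated correlation). The sulfotransferase Sult1d1 rose by 1.62 (SE 0.26) and the kinase Sgk1 by 0.96 (SE 0.20), which was 0.41 after quantile normalization (adjusted p = 0.0819). Prap1, a secreted protein of the uterine epithelium, rose by 2.19 (SE 0.50), or by 2.88 without Stat3 d/d replicate 3. The progesterone receptor gene Pgr fell from 1261 to 694 (-0.84, SE 0.20).

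Of the uterine gland genes in the table, 5 of 7 were lower, with a median of -0.83 (adjusted p = 0.0393, and adjusted p = 0.267 with an estimated correlation). That call was also lost after quantile normalization (0.0762), after median centring (0.0826) and without the dimmest genes (0.0977). Cfi fell as above, the stem-cell marker Lgr5 by 1.91 (SE 0.42) and the retinaldehyde dehydrogenase Aldh1a1 by 1.91 (SE 0.43). Fxyd4, a regulator of the sodium pump, rose by 1.78 (SE 0.39). Without Stat3 f/f replicate 4 these 3 values became -1.27, -1.25 and 1.19. Of the Wnt pathway genes in the table, 5 of 7 fell, among them the Wnt antagonist Sfrp1 (-1.76, SE 0.23) and the ligand Wnt4 (-1.40, SE 0.33). Wnt5b rose by 0.91 (SE 0.17). The Wnt list's median was -0.82 (adjusted p = 0.0481; adjusted p = 0.393 with an estimated correlation), and the call was lost without Stat3 d/d replicate 1 (0.0577) or replicate 2 (0.0565), and under 5 other settings.

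Of the extracellular matrix genes in the table, 6 of 7 fell (median -0.82, adjusted p = 0.0142, and adjusted p = 0.250 with an estimated correlation). The stromelysin Mmp3 fell by 1.23 (SE 0.22), and the small proteoglycans Dcn and Fmod by 1.06 (SE 0.22) and 1.31 (SE 0.29). Dcn was read by a dim probe set, at 27.6 ± 6.58 in Stat3 f/f and 12.7 ± 2.71 in Stat3 d/d. Any probe set of Dcn outside the table was not analysed, so its total level stays open. Thrombospondin, Thbs1, rose by 0.75 (SE 0.17). For ion, water and solute transport, 8 of 11 rose (median 0.96; adjusted p = 0.844; 0.887 with an estimated correlation): the amino acid transporter Slc6a14 by 2.48 (SE 0.36; 1.70 averaged over its probe sets) and the water channel Aqp8 by 1.63 (SE 0.28), while Aqp4 (-1.05, SE 0.17) and Fxyd2 (-1.30, SE 0.19) fell. After either scaling 4 transport genes were higher and 3 lower past the threshold. Epithelial junction genes went both ways, 4 up and 3 down. After either scaling 0 of the rises and all 3 falls passed, which follows from the scalings, as they lower the changes. The gap junction gene Gjb2 fell by 1.84 (SE 0.42) and the tight junction gene Cldn2 by 0.72 (SE 0.19), while Cldn4 and the desmosomal Ppl rose by 0.68 (SE 0.17) and 0.73 (SE 0.20). Their median was 0.66 although the test against other genes pointed down (adjusted p = 0.543), so the median and the test differed in sign.

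The remaining lists had too few genes in the table for a test. Cyclin D1, Ccnd1, fell by 0.59 (SE 0.16) on its brighter probe set and by 2.04 on the other, the glycolytic enzyme Aldoc by 1.36 (SE 0.25), and the centromeric histone Cenpa rose by 0.86 (SE 0.18). Of epithelial markers, the claudins Cldn3 (0.74, SE 0.21) and Cldn4 were higher. Among stromal markers Pdpn (0.77, SE 0.16) and Tcf21 (0.74, SE 0.17) rose, while Dcn and Thy1 (-0.76, SE 0.21) fell. The smooth muscle genes Cald1 (-1.09, SE 0.22) and Ldb3 (-0.73, SE 0.16) fell and Synpo2 rose (0.75, SE 0.20). Cald1, like Dcn, was read by a dim probe set, with means of 33.8 in Stat3 f/f and 14.9 in Stat3 d/d. The endothelial Sox7 fell (-1.12, SE 0.24) and the lymphatic marker Lyve1 rose (0.82, SE 0.22). Ighm (0.89, SE 0.24), the mesothelial Upk3b (0.74, SE 0.21) and Gpm6a (0.66, SE 0.17) and the metabolic enzyme Pck1 (0.88, SE 0.16) rose, and the lipase Lpl fell (-0.72, SE 0.20). With median centring or quantile normalization, Cenpa, Cldn3, Cldn4, Pdpn, Tcf21, Synpo2, Lyve1, Ighm, Upk3b and Gpm6a no longer passed, nor did Thbs1 and Ppl; Pck1 no longer passed with quantile normalization. No gene of the lists for the hedgehog pathway, neutrophils and eosinophils, mast cells or blood was in the table.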

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

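The settings with no pseudocount, no variance moderation, 45000 assumed tests and the STAT3 list without Stat3 were chosen after the data were seen; the others were planned. The 1382 probe sets became 887 with quantile normalization, 873 with median centring, 518 over 45000 assumed tests and 17 over that number without variance moderation. The 1269 probe sets changed at least 1.5-fold by log2(intensity + 1) became 815, 796 and, at 2-fold, 528. The 987 genes became 624, 618 and 311. Both scalings remove a shift towards higher values in Stat3 d/d, and a larger number of tests raises each adjusted p, so these falls follow from the settings. The 10 lists past the threshold became 0 with an estimated correlation. Of 89 named genes besides Stat3, none reversed under the settings run, 15 lost their call with median centring, 18 with quantile normalization and 36 over 45000 assumed tests. As no probe set has overlapping groups, leaving out an array could not reverse the direction of these genes or of Stat3. The sign of the list test reversed for chemokines under the replicate block (adjusted p = 0.912, pointing down), and the cause was not tested. For epithelial junctions it reversed with fry (adjusted p = 0.417, pointing up). Unlike camera, fry follows the list's own changes and does not compare them with the other genes of the table. Neither was a call. The replicate block gave 1284 probe sets and 913 genes and ended no call of a named gene. Only numbers 1 and 2 occur in both groups, with correlations of their deviations of 0.0878 and 0.0284. Pairs with different numbers ranged from -0.150 to 0.161. These values therefore cannot show whether arrays of the same number share a litter or day. Stat3 kept its direction and call under the settings run. Signal over background was not analysed here, so dim genes cannot be told from background.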

Other observations

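The gene families and all tests of explanations here except those on other splits of the arrays were chosen after the values were seen. The 11 GTPases of the Gbp and Irg families in the table, which restrict intracellular pathogens, all rose, by 1.12 to 3.50 (median 2.62), and all 11 were still higher past the threshold after median centring and after quantile normalization. Irgm2 rose from 41.7 ± 6.73 to 277 ± 2.71 (2.72, SE 0.18). All 7 Klr receptors of natural killer cells rose (median 1.14), with 4 past the threshold after median centring and 5 after quantile normalization. All 4 Fc receptor genes rose (median 1.44), with 3 past it after either scaling; Fcgr4 rose 3.61-fold (1.85, SE 0.22). The 5 granzymes rose, with 2 past the threshold after median centring and 4 after quantile normalization. The other families examined went both ways: Trim genes 6 up and 2 down, integrins 4 and 2, Zfp genes 14 and 5, solute carriers 15 and 6, and histones 2 and 2, where 67.4% of all probe sets were higher. Counting only genes past the threshold after median centring, these were 5 and 2, 4 and 2, 8 and 5, 8 and 6, and 1 and 2. With quantile normalization only solute carriers differed, at 9 and 6.

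No other of the 10 splits of the 6 arrays into 3 and 3 called any probe set or gene: the real split gave 1382 probe sets, 1269 of them at least 1.5-fold by log2(intensity + 1) rather than by the ratio of means, and 987 genes, and the highest other split gave 0 of each, so 1 split, the real one, reached these counts. 10 splits are too few for a share under 0.05, and the table was selected on the real split.

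The rise of interferon-stimulated genes came with a rise of leukocyte markers. A larger share of leukocytes may account for both, or the genes may have risen within the cells already there. The median of the 34 interferon genes exceeded that of the 24 leukocyte markers by 0.0496 (95% bootstrap interval -0.288 to 0.484, one-sided permutation p = 0.342 with 100000 resamples). These medians cannot tell the 2 explanations apart, since both lists hold only genes past the same selection. Without Stat3 d/d replicate 1 the interferon median was 1.38, against 0.997 for macrophage and 1.16 for T and NK cell markers. Without Stat3 f/f replicate 4 the medians were 1.41, 0.960 and 1.19. With all arrays they were 1.30, 1.25 and 1.30. The lists therefore did not shift together in these cases, but each rests on leaving out 1 array, so the 2 explanations stay open. Of the markers, 4 had a mean of 100 or more in Stat3 f/f, Lyz1 the highest at 847, and it rose to 2000, while 1 of the 24 stands on another fixed list; the effect of Stat3 loss itself stays open and untested.

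Several changes of 4-fold or more concern genes of no shared function. Probe sets that read a sequence or transcript variant are a candidate explanation for some: of 25 genes with a 4-fold probe set and several probe sets, 6 had probe sets in opposite directions, among them Xaf1, Trim34a and Riok3, against 9 of 138 others (odds ratio 4.47, Fisher's exact p = 0.0138, two-sided; 6.52, p = 0.00424, within classes of probe set number). For Paip1 the 2 probe sets gave -2.23 and -2.22, which does not decide it, as the part of the transcript they read was not examined. Tmem87a, Rps9 and Mtrex have no second probe set in the table. Chromosome segments of another strain background remain open, since 6 pairs of differently named genes lay within 10 gene positions (mean of 10000 draws 3.16, permutation p = 0.111), and 4 with immune families left out (1.53, p = 0.0716), among them Paip1 with Tmem267 (2.75). A segment around Stat3 from the strain the allele was made in also remains open: of the 200 protein-coding genes around it 5 were in the table and 0 of these changed 4-fold, but the median window held 0 too, and 7 of the 71 placed genes with any probe set changed 4-fold lay on its chromosome (55 of 873 others, exact p = 0.219); no biological explanation was tested.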
